A study of Mus musculus with 7 samples.

How the data were processed

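Chromatin immunoprecipitation with sequencing (ChIP-seq) of the nuclear receptor HNF4a, with antibody ab41898, was carried out on mouse liver. Per the labels, the mice received doxycycline in a high-fat diet, over 14 days. There were 3 wild-type (WT) libraries and 3 libraries from mice with constitutively active AMP-activated protein kinase (AMPK-CA). Each of 3 labelled batches held 1 library of each genotype. A pooled input library was not analysed here, since no column of the table used carries its name. Chromatin was lysed in Active Motif buffer and libraries were made with a Takara PrepX or an NEB kit, per the labels' protocols, which do not say which library had which kit.

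The submitters' processing notes name Trim Galore, FastQC, BWA, SAMtools, Picard, deepTools, MACS2, SICER and HOMER, without roles or versions, and the builds GRCm38 and mm10. The table used lists 39704 regions in mm10 coordinates, counted from 1, each with an annotation, a gene and a distance to a transcription start site (TSS), per the file headers. How the regions were selected is not given in the sources used here; the interval numbers in the table reach 138145. A gene name below is the gene that the table assigns to a region, which can differ from the gene in whose intron the region lies. No genome sequence was used, so motifs were not searched.

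The deposited signal of each library is a normalized read number per region. In each library 100% of these values were whole multiples, within 1e-09, of the smallest non-zero value, so whole reads were recovered. The 6 libraries held between 536027 and 1622087 reads in regions. The divisor that the authors used for each library lay close to a median-of-ratios size factor computed from the recovered reads, with ratios of 1.04 in 5 libraries and 0.992 in WT replicate 1. Such a scale takes out any change shared by most regions. Total sequencing depth outside the regions is unknown, so a change of HNF4a binding common to all regions cannot be measured from these values. Values are not divided by region length, which ran from 201 to 4329 bp.

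The authors' deposited table also holds AMPK-CA over WT ratios for each experiment and the log2 of their mean. The columns headed ratio 2 and ratio 3 hold experiments 3 and 2, as recomputed from the library columns. The deposited p-value of every region for which it could be recomputed equals an equal-variance test of the 3 ratios against 3 values of 1, and was not adjusted for multiple testing. The 3 values of 1 carry no spread, yet the test counts them as data, so its p-values are too small. The deposited score equals log2 mean ratio times −log10 of that p-value. Blank lines divide the promoter regions of the authors' deposited table at scores of -0.75 and 0.75.

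Before the data were examined, the test for normalized values was fixed as limma with a mean-variance trend and robust empirical Bayes on log2(value + 1.80), the pseudocount being 0.1 times the median non-zero value, with genotype as the term and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this log2(value + pseudocount) scale, which understates changes of weak regions, and as differences of mean log2 values they can differ from the log2 of a ratio of means. The fit with labelled batch as a block was fixed as the alternative. The label makes the batch a pairing of the samples. The deviations of same-batch libraries from their genotype means correlated across regions with r of 0.53, 0.49 and 0.05 in batches 1, 2 and 3. Blocked values therefore stand beside the others. No pair of libraries was a duplicate: chi-square per degree of freedom was 1.58 or more for all 15 pairs. The planned test was for values or counts, and the unit found was normalized signal, so count tests on the recovered reads (edgeR quasi-likelihood and DESeq2) were added as alternatives. The labels name the libraries by separate animal codes. Limma p-values draw on the spread between these libraries and on the mean-variance trend over all regions. They therefore do not measure a region's own spread alone. At a Ppp2r2b region, within-batch differences of -4.26, -3.93 and 0.02 stood beside a blocked standard error of 0.41.

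Regions were named by a rule fixed in advance. In each direction it took regions past the threshold, or, where fewer than 5 passed, the 5 with the smallest p, with all 3 within-batch differences of the same sign and a mean at or above the median of all regions. It also took the 2 most strongly bound genes of each gene list, Hnf4a and the AMPK subunit genes. Some genes that the rule takes are not reported here. Regions called only with the batch block were named after their values were seen. For 23 gene lists fixed in advance, each gene was represented by its most strongly bound region within 50 kb of its TSS. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Single values per library were compared by exact two-sided permutation tests, in which 3 against 3 libraries cannot give p below 0.1. These tests leave out the pairing by batch. Promoter shares were compared by two-sided Fisher's exact test.

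Counting error limits each value. The median region held between 10 reads in WT replicate 3 and 28 in WT replicate 1, for a Poisson coefficient of variation of 31.6% and 18.9%. The median standard error of a region's log2 fold change was 0.48 without and 0.41 with the batch block. The fits were tested on simulated data drawn from the real means, batch effects and dispersions, with 100 of the 39704 regions changed by a log2 of 1 and 100 by a log2 of 2. The changed regions were drawn from those with a mean at or above the median, so recovery in weaker regions was not measured. Without the block 0% and 28% of the changed regions were called, with 0 false calls. With the block 16% and 92% were called, with 7 false calls, and edgeR with the block gave 17% and 92%, with 5 false calls. The simulation gave both libraries of a batch the same batch effect and used dispersions fitted with the block. In the real data same-batch deviations correlated at only r = 0.05 in batch 3, so the figures with the block may be optimistic.

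Alternatives were other pseudocounts, median centring, quantile normalization, no trend, a filter on weak regions, library weights, other rules for a gene's region, and leaving out libraries or batches. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.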

Results

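HNF4a occupancy was measured by ChIP-seq in livers of wild-type mice and of mice with constitutively active AMPK, the kinase that senses low cellular energy. The design asks how binding of HNF4a, a nuclear receptor that drives hepatocyte gene expression, differs between the genotypes on a high-fat diet with doxycycline. Each group had 3 libraries, 1 per labelled batch. The 39704 regions comprised 17813 in introns, 12425 between genes, 5235 at promoters, 3511 in exons and 720 at gene ends, and named 13644 genes. The WT libraries held 1622087, 1360605 and 536027 reads in regions in batches 1, 2 and 3, and the AMPK-CA libraries held 1207609, 1037428 and 692813. WT replicate 1 had 19.4% of its reads at promoters and AMPK-CA replicate 1, of the same batch, 14.2%, against 11.7% to 13.4% in the other 4. Across regions the log2 values of WT replicate 1 correlated with those of AMPK-CA replicate 1 at r = 0.74 and with those of WT replicates 2 and 3 at r = 0.43 and 0.55, where WT replicates 2 and 3 correlated with each other at r = 0.72.

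The difference between genotypes with the smallest p lay upstream of Alb, the gene of serum albumin. A region 10.6 kb upstream of its start site (chr5:90449974-90450596, intergenic, mm10) had 16.7 ± 12.1 normalized reads in WT and 85.5 ± 15.9 in AMPK-CA (mean ± SD, n = 3 each). The ratio of these means was 5.12, and the log2 fold change, a difference of mean log2 values, was 2.55 ± 0.47 (SE), with within-batch differences of 3.84, 1.86 and 1.96 in batches 1, 2 and 3. A second region 9.7 kb upstream (chr5:90450992-90451397) had 7.61 ± 5.32 and 28.1 ± 3.02, and the Alb promoter region (chr5:90460441-90460952) had 17.3 ± 9.64 and 59.5 ± 24.9. The promoter of Nr1i3, which encodes the xenobiotic receptor CAR (chr1:171213647-171214430, 69 bp from the start site), went the other way, with 121 ± 31.5 in WT and 48.9 ± 13.7 in AMPK-CA, a log2 fold change of -1.28 ± 0.30.

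By limma without the batch block, 0 of the 39704 regions passed an adjusted p of 0.05. The smallest adjusted p was 0.664, at the Alb region 10.6 kb upstream, and 975 regions had an unadjusted p under 0.05, of which 580 were higher and 395 lower in AMPK-CA, where chance alone would give 1985.2. With batch as a block, limma called 23 regions, 18 higher and 5 lower, and 2888 had an unadjusted p under 0.05. The count was 0 by edgeR without the block (830 unadjusted), 24 by edgeR with it and 1 by DESeq2 with it, the Alb region 10.6 kb upstream. Limma with the block but no mean-variance trend called 0 (2715 unadjusted), so that the Alb calls were lost with the rest. Limma with library weights and no block called 922, with WT replicate 3 weighted most. Leaving out WT replicate 1 gave 16 calls without the block, 7 of them among the 23, and leaving out WT replicate 2 or AMPK-CA replicate 3 gave 1 each. The blocked count was 12, 2 and 7 without batches 1, 2 and 3, of which 8, 2 and 6 were among the 23.

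With the batch block, the read signal rose at all 3 Alb regions named above, with adjusted p of 6.62e-11, 0.030 and 1.20e-03 in order of distance to the start site, farthest first. Without batch 1 the region 9.7 kb upstream was not called, at a log2 fold change of 1.30 against 1.86 with all batches, and the region 10.6 kb upstream was called at 1.91. Input reads were not analysed here, so HNF4a binding and the number of copies of this DNA were not separated. A region 7.3 kb upstream of Sult4a1, a sulfotransferase family gene (chr15:84112745-84113398, in the last intron of Pnpla5), had 30.6 ± 12.2 in WT and 92.8 ± 19.8 in AMPK-CA, with a blocked adjusted p of 1.08e-04. Intron 1 of Muc13, which encodes a transmembrane mucin (chr16:33794014-33794815), had 12.9 ± 2.95 and 48.0 ± 4.41, with a blocked adjusted p of 3.15e-03. Intron 19 of Mtor, the growth-promoting kinase opposed by AMPK (chr4:148472457-148472827), had 8.30 ± 4.29 and 36.3 ± 10.7, with a blocked adjusted p of 3.88e-03. A region assigned to Cebpg, a bZIP factor gene (chr7:35029226-35029793, in intron 11 of Pepd), had 12.5 ± 4.84 and 43.5 ± 2.10, with a blocked adjusted p of 0.011. None of these passed without the block in the limma fit fixed in advance or by edgeR. With library weights and no block, limma called 19 of the 23 regions of the blocked fit among its 922 calls. The weights there were 3.46 for WT replicate 3, and 0.253 and 0.568 for WT replicates 1 and 2. The WT mean of that fit therefore rested mostly on WT replicate 3, the shallowest library. Without WT replicate 1 and the block, limma called 7 of the 23.

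Among lower regions, Nr1i3 fell with the block (adjusted p 1.20e-03), as did a region 1.2 kb upstream of Ociad2 (chr5:73339468-73340241), from 88.1 ± 4.24 to 38.8 ± 7.69 (adjusted p 0.030), and intron 2 of 4933406C10Rik (chr12:32929830-32930641), from 46.6 ± 19.7 to 13.7 ± 6.67 (adjusted p 0.014). Intron 1 of Ifi47, an interferon-inducible GTPase gene, had 61.4 ± 21.3 and 23.1 ± 4.37. A region near Thnsl2 had 56.9 ± 9.34 and 25.3 ± 4.63. Neither passed with the block (limma adjusted p 0.051 and 0.203). Without batch 1 the blocked limma fit called Ifi47 (log2 fold change -1.73, adjusted p 9.96e-04) but not Thnsl2 (adjusted p 0.427). The blocked fit of all batches called 2 further lower regions. The last exon of Adi1, assigned to Mir6937 (chr12:28681633-28682186), had 27.9 ± 5.86 and 3.04 ± 2.19, a log2 fold change of -2.69, larger in size than that at Alb. Intron 1 of Ppp2r2b, which encodes a regulatory subunit of protein phosphatase 2A (chr18:42975813-42976165), had 49, 54 and 41 reads in WT but 0, 1 and 54 in AMPK-CA replicates 1, 2 and 3. Its blocked adjusted p was 4.11e-07 by limma and 0.25 by edgeR. The remaining higher calls were assigned to Amigo2, Zfp462, Gm20756, Sqrdl, Pde3a, Mir466o, Mir6367, C630031E19Rik, Brca1, Dynlrb2 and Tra2b. Their log2 fold changes lay between 1.29 at Brca1, in exon 10 of that DNA repair gene, and 2.15 at C630031E19Rik. Without batch 1, the 8 calls left among the 23 were Alb at 10.6 kb and at its promoter, Sult4a1, Muc13, Cebpg, Mtor, Nr1i3 and Ppp2r2b. The log2 fold change then went from 1.73 to 0.88 at Amigo2 and from 2.15 to 1.41 at C630031E19Rik. EdgeR with the block did not call Ppp2r2b or Tra2b.

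**Figure D1:**
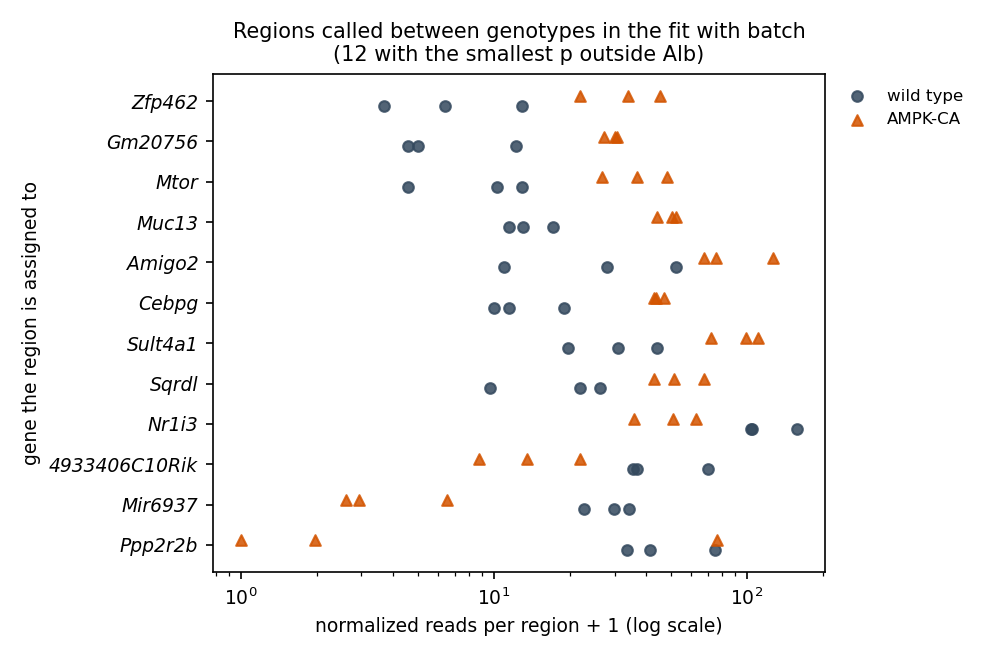
Normalized reads per region plus 1 (horizontal log axis) in each of the 3 WT (circles) and 3 AMPK-CA (triangles) libraries, for the 12 regions outside Alb with the smallest p in the fit with batch. The groups do not overlap except at Ppp2r2b, where AMPK-CA replicate 3 lies with the WT libraries.

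**Figure D2:**
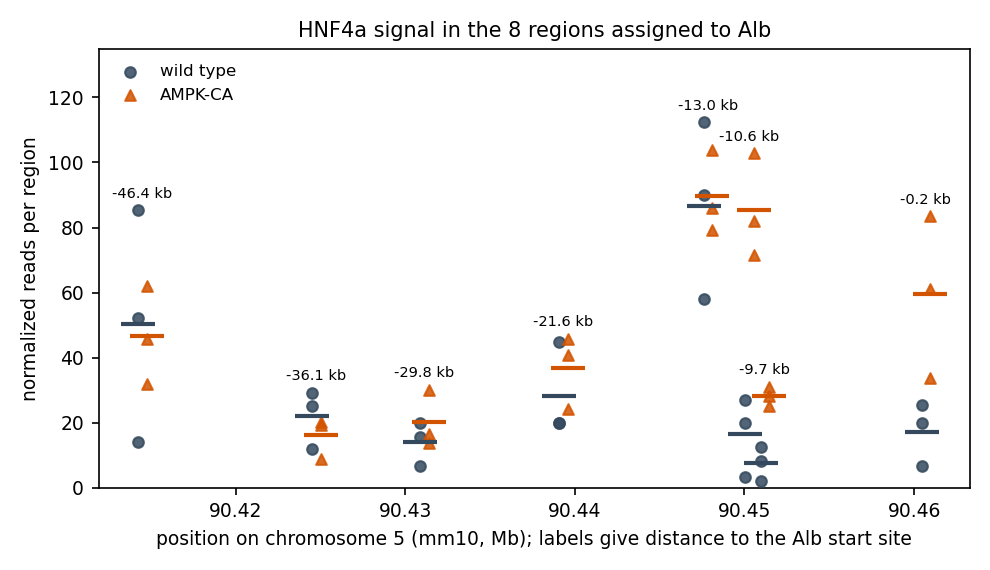
Normalized reads per region (vertical axis) in the 8 regions assigned to Alb, by position on chromosome 5; points are libraries and horizontal bars are means of 3. The regions 10.6 kb and 9.7 kb upstream and the promoter are higher in AMPK-CA, and the region 13.03 kb upstream has means of 86.7 and 89.7.

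The level of HNF4a signal over all regions differed between the genotypes by less than the spread among libraries on the authors' scale. The median log2 value per library was 4.30 ± 0.053 in WT and 4.29 ± 0.022 in AMPK-CA (SD, n = 3), a difference of -0.015 (exact two-sided permutation p = 0.7, where 0.1 is the smallest possible). The within-batch differences were -0.070, 0.018 and 0.006 in batches 1, 2 and 3. Without WT replicate 1 the difference was 0.011, and on the scale of total recovered reads it was 0.037. Because the scale takes out a shared change, these values do not measure one.

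Promoter regions had a median log2 value of 4.46 ± 0.50 in WT and 4.21 ± 0.18 in AMPK-CA, and exon regions had 4.27 ± 0.55 and 4.08 ± 0.22 (SD, n = 3). The promoter difference of -0.25 was smaller than the spread among WT libraries (exact permutation p = 0.6, without the pairing by batch). Within batches 1, 2 and 3 it was -0.62, -0.04 and -0.10, so that batch 1 contributed most of it. Without batch 1 it was -0.07. All 3 within-batch differences were negative, but sign flips of 3 pairs cannot give p below 0.25. For exons the difference of -0.20 became -0.005 without batch 1. Intron and intergenic regions differed by 0.014 and 0.042, and by 0.012 and 0.0008 without batch 1. Regions at gene ends differed by -0.15, and by -0.09 without batch 1. A camera test of promoters against other regions gave p = 1.16e-10 at the preset correlation but p = 0.266 with an estimated correlation, 0.246 with the estimated correlation and the batch block, and 0.058 with both and without batch 1. The fit without batch 1 leaves too few degrees of freedom to estimate the correlation, so its p is not comparable with the others. Promoter regions with an unadjusted limma p under 0.05 numbered 10 higher and 111 lower without the block, 51 and 364 with it, and 91 and 179 with it and without batch 1.

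**Figure D3:**
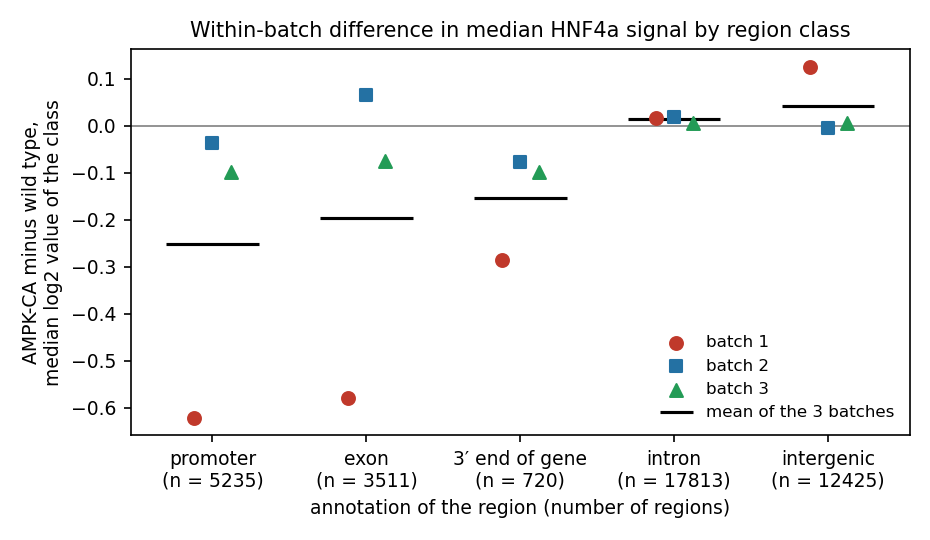
Difference in median log2 value between AMPK-CA and WT (vertical axis) within batches 1, 2 and 3 (points) and their mean (bar), by annotation of the region. Promoters and exons lie at -0.62 and -0.58 in batch 1, and between -0.10 and 0.06 in the other batches.

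In the authors' deposited table, 788 promoter regions had a score below -0.75 and 118 a score above 0.75. Over all regions that table gave an unadjusted p under 0.05 to 3458 regions with a mean ratio below 1 and 1484 above. As the p-values of that test are too small, the chance number given for limma does not apply to these counts. Of the 788 promoter regions, 1 was called by limma with the block, and 297 had an unadjusted blocked p under 0.05, against 107 without the block. Of the 23 regions called with the block, 3 lay within 1 kb of a start site, 13.04%, against 23.2% of the other regions (Fisher's exact p = 0.327). Within 5 kb it was 5 of 23 (Fisher's exact p = 0.135). Of the 18 higher calls 2 lay there, 11.1% against 37.7% of the other regions (Fisher's exact p = 0.026), and of the 5 lower calls 3 (Fisher's exact p = 0.372). These p-values are not adjusted for the distances and directions tried, and higher calls were not tested against lower ones. The fit without the block called none, so its promoter share has no value.

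Of the 22 genes with a region for liver transcription factors, the network that specifies hepatocytes, 20 had a negative and 2 a positive log2 fold change, with a median of -0.28. In this and the other lists, higher and lower members are counted by the sign of that log2 fold change, which can differ from the sign of the difference in means. A region near Nr2f6, an orphan nuclear receptor gene, had 169 ± 55.0 in WT and 138 ± 8.22 in AMPK-CA. The list passed camera only at the preset correlation (adjusted p = 8.76e-03, 0.014 with the batch block), with adjusted p = 0.953 with an estimated correlation and 0.972 by fry. By limma and by edgeR 0 members were called over all regions, without or with the block, and by limma 0 when adjusted over the list alone; 0 had an unadjusted p under 0.05 without and 3 with the block. Without batch 1 its median was -0.06 and its camera adjusted p 0.633. The promoter share was highest in WT replicate 1, and the log2 difference at Nr2f6 was -0.82 in batch 1, -0.14 in batch 2 and 0.25 in batch 3.

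Of 26 genes of fatty acid oxidation and ketone synthesis, 15 had a positive log2 fold change, with a median of 0.12, and the list did not pass (camera adjusted p = 0.238). By limma 0 of its members were called over all regions, without or with the block, and when adjusted over the list alone 0 were called without and 1 with the block, a call lost without batch 1; 1 had an unadjusted p under 0.05 without and 3 with the block, and edgeR called 0 over all regions. Ppara, the receptor that controls this pathway, had 194 ± 73.7 in WT and 174 ± 10.2 in AMPK-CA at its promoter, and Acaa2 had 92.4 ± 29.3 and 91.9 ± 22.8. Lipid uptake and droplet genes were higher in 11 of 21 (median 0.04, adjusted p = 0.587), with Cideb at 132 ± 32.2 and 114 ± 22.5 and Lipc, hepatic lipase, at 93.1 ± 18.0 and 108 ± 41.2. Intron 1 of Slc27a2, a fatty acid transporter gene of this list, had 47.7 ± 24.6 and 80.1 ± 16.5. With the block it was the 1 member called when adjusted over the list alone, and it was not called over all regions. Without batch 1 its blocked log2 fold change went from 0.85 to 0.46 and that call was lost.

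The list of cytochrome P450 and drug metabolism genes, 15 of 23 higher with a median of 0.22, did not pass (camera adjusted p = 0.220). Without batch 1 its median was -0.06, with 11 of 23 higher. Nr1i3 belongs to that list and was its only member called when adjusted over the list alone, without or with the block, and was the only listed gene whose strongest region was called over all regions with the block. Its most strongly bound genes were Cyp2d10 at 113 ± 12.6 and 130 ± 20.04 and Cyp2d22 at 133 ± 40.6 and 95.3 ± 7.42. Of 6 cholangiocyte marker genes with a region, 4 were lower, with a median of -0.44 (adjusted p = 0.220), or -0.19 without batch 1. Among them Slc4a2, an anion exchanger gene, had 37.9 ± 19.1 and 13.9 ± 2.90. It was among the 2 members called with the block when adjusted over the list alone, of which 0 were called without batch 1. Spp1, osteopontin, had 24.4 ± 8.39 and 29.6 ± 12.8.

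The other lists also did not pass camera. Genes of fatty acid and triglyceride synthesis had a median of -0.06 (9 of 19 higher, camera adjusted p = 0.953). Among them Mlxipl, the sugar-responsive factor ChREBP, had 208 ± 61.5 and 175 ± 8.47, and Agpat2 had 138 ± 27.0 and 122 ± 28.0. Cholesterol synthesis had a median of -0.15 (8 of 20 higher, adjusted p = 0.587), with Insig1 at 132 ± 46.0 and 130 ± 13.1. Genes of glucose production and other glucose metabolism had a median of 0.006 (9 of 15 higher, camera adjusted p = 0.587). Among them the glycogen synthase gene Gys2 had 171 ± 3.14 and 184 ± 12.8, and G6pc had 157 ± 52.1 and 149 ± 37.2. Glycolysis had a median of -0.12 (1 of 10 higher, adjusted p = 0.587), with Ldha at 139 ± 18.1 and 136 ± 22.5 and Gapdh at 123 ± 56.8 and 96.9 ± 11.3. Apolipoprotein and other lipoprotein genes had a median of -0.11 (5 of 16 higher, camera adjusted p = 0.587), with Tm6sf2 at 137 ± 34.2 and 147 ± 9.73. Coagulation and complement genes had a median of -0.07 (12 of 27 higher, adjusted p = 0.587), with Cfb at 160 ± 21.7 and 136 ± 17.1. Bile acid genes had a median of 0.02 (9 of 18 higher, adjusted p = 0.587), with Akr1d1 at 169 ± 73.1 and 166 ± 69.5. Urea and amino acid genes had a median of -0.13 (9 of 22 higher, adjusted p = 0.887), with the urea cycle gene Ass1 at 179 ± 9.48 and 149 ± 14.1.

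Cell cycle genes had a median of 0.04 (8 of 15 higher, adjusted p = 0.887), with Cdk1, the mitotic kinase, at 74.4 ± 0.871 and 98.7 ± 13.8 and Mki67 at 59.3 ± 12.7 and 70.6 ± 14.6. Fetal liver and liver cancer genes had a median of -0.16 (6 of 13 higher, adjusted p = 0.95), with Afp, alpha-fetoprotein, at 90.7 ± 31.3 and 94.4 ± 14.3. Inflammation and acute phase genes had a median of -0.04 (7 of 18 higher, camera adjusted p = 0.587), with Cxcl1 at 120 ± 35.8 and 114 ± 13.8. Mitochondrial regulators had a median of -0.06 (5 of 15 higher, adjusted p = 0.587), with Sirt3 at 86.1 ± 48.3 and 86.7 ± 15.04, and autophagy and lysosome genes a median of -0.01 (8 of 17 higher, adjusted p = 0.587), with Tfeb at 92.1 ± 47.6 and 99.6 ± 4.33. Markers of stellate cells (median -0.22), Kupffer cells (0.02) and endothelium (-0.35) had only 3, 3 and 6 regions, with adjusted p of 0.887, 0.587 and 0.887. Housekeeping genes were lower in 12 of 14, with a median of -0.18 (adjusted p = 0.25). In these 17 lists 0 members were called over all regions by limma or edgeR, without or with the block, and 0 by limma when adjusted over the list alone. Unadjusted limma p was under 0.05 for 4 members without the block, among them Foxo1 and Cdk2, lower in AMPK-CA, and Vwf, higher, and for 15 with it. The camera direction was up against a negative median for the coagulation, fetal liver, acute phase, autophagy and AMPK subunit lists. The mean and the median differed in sign for the coagulation, cell cycle and acute phase lists. Without batch 1 the median changed sign for the bile acid, urea and amino acid, cell cycle, fetal liver, acute phase, autophagy and Kupffer cell lists.

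At Hnf4a itself the strongest region lay in intron 5 (chr2:163559174-163559684), with 24.3 ± 3.23 in WT and 31.1 ± 11.9 in AMPK-CA. For the AMPK subunit genes the values were 61.8 ± 22.2 and 77.4 ± 2.92 at Prkag2, 76.3 ± 15.99 and 58.9 ± 12.9 at Prkab1, and 34.0 ± 15.3 and 29.9 ± 10.3 at Prkab2. Prkaa1 and Prkaa2, the catalytic subunit genes, had 18.5 ± 11.1 and 19.98 ± 7.84, and 15.7 ± 8.45 and 15.8 ± 6.58. Prkag1 and Prkag3 had 8.76 ± 6.50 and 7.65 ± 6.71, and 30.9 ± 10.1 and 24.9 ± 6.99. Of these 8 genes 0 were called by limma or edgeR, and 0 had an unadjusted limma p under 0.05, without or with the block, and the AMPK subunit list had a median of -0.13 and a camera adjusted p of 0.95. Without batch 1 the median of that list was -0.33, with 5 of 7 genes lower.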

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

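The count tests, library weights, left-out batches, the promoter signal, the use of blocked calls for the promoter share, the threshold of 0.1 for the blocked count and the blocked settings other than median centring were chosen after seeing the data; the other alternatives were fixed before. The count of 0 regions without the block became 23 with the replicate block, 24 with the block and median centring, 1 with quantile normalization, 24 by edgeR and 1 by DESeq2 with the block, 922 with library weights and 30 with weights and the block, and between 0 and 16 when 1 library was left out. It stayed at 0 with median centring, no trend, the filter on weak regions, both pseudocounts and edgeR without the block. The blocked count of 23 became 1 by DESeq2, 0 without the trend, 0 with no replicate block, and between 2 and 12 without 1 batch. The weights were 0.253 for WT replicate 1 and 3.46 for WT replicate 3. The number of gene lists, 1, became 2 within 10 kb, 0 with the region nearest the start site, 0 with all assigned regions, 0 with an estimated correlation, and between 0 and 2 without 1 library; without batch 1 it was 0. The cause of these changes was not tested. Leaving out libraries leaves fewer samples, which by itself does not account for the rise from 0 to 16 without WT replicate 1. Calls shared with the 23 numbered 8, 2 and 6 without batches 1, 2 and 3, 21 by edgeR with the block and 19 with library weights. The block changed no other list's camera call. Other results are counted as pairs of a list, or of a named region, with 1 alternative. Of the list pairs, 242 kept their call, 51 of them with another sign, 5 gained and 6 lost it. Of the region pairs, 1948 kept it, 130 with another sign, and 221 gained it. No called value changed sign. The promoter share of all calls stayed on the same side of the threshold, though within 5 kb the higher calls alone had Fisher's exact p = 0.026. For the signal over all regions no alternative could pass, since the exact permutation p cannot go below 0.1. Its sign changed without WT replicate 1 (0.011) and on the scale of total recovered reads (0.037). Alternatives that need calls per library, peak heights or an input column were not run, since the table used here has none, and the settings for raw counts did not apply. Small changes are often missed: 16% of simulated log2 changes of 1, in regions with a mean at or above the median, were called with the block. Depth was not varied, so its part in this cannot be told apart from the spread between libraries and their number.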

Other observations

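In this part the tests of gene coverage, of the Alb regions against farther regions, of depth and of batch in WT replicate 1, of nearly empty regions against the batch partner, and the exchange of genotype within a batch were chosen after the result was seen; the others were set before their result. The most strongly bound region of the table was assigned to Ndufv1, a subunit gene of respiratory complex I, 11.8 kb upstream of its start site, with a mean of 406.6 normalized reads over the 6 libraries. Other regions among the 15 strongest were assigned to Nrip1, a nuclear receptor corepressor gene (296.9), Nfe2l2, which encodes the oxidative stress factor NRF2 (270.7), Lifr, a cytokine receptor gene (245.7), and Nr3c1, the glucocorticoid receptor gene (239.9). Of 134 listed genes of hepatocyte functions (apolipoproteins, coagulation, fatty acid oxidation, bile acids, cytochrome P450 and urea), 132 had a region within 50 kb, against 18 of 50 markers of stellate, Kupffer, endothelial and cholangiocyte cells (Fisher's exact p = 1.23e-20). Their median values were 51.0 and 26.5, against 24.7 over all genes with a region. High coverage was not particular to hepatocyte functions. A region was found for 14 of 15 housekeeping, 17 of 18 autophagy and lysosome and 15 of 16 mitochondrial genes. Cell cycle and glycolysis genes had 15 of 22 and 10 of 18.

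The 3 Alb regions within 11 kb of the start site had log2 fold changes between 1.75 and 2.55, and the 5 farther upstream between -0.40 and 0.50. Library scaling as the cause is argued against by the region 10.6 kb upstream, whose log2 fold change was at least 2.00 under every scaling and pseudocount tried for it. A rise along the whole upstream region is argued against by the median of 0.16 in the farther regions. The near and far medians differed by 1.71 (exact p = 0.054 over the 56 ways to pick 3 of 8 regions). A candidate explanation is extra copies of Alb enhancer and promoter DNA in a transgene carried by the AMPK-CA mice, but the labels name no driver, the distance was set after the values were seen, and a change of HNF4a binding at these elements alone stays open.

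WT replicate 1 differed from WT replicates 2 and 3 by a median log2 of 0.97 in regions within 1 kb of a start site and -0.28 elsewhere. Depth alone is argued against by WT replicate 2, the next deepest, with 12.1% of reads at promoters, below the 13.4% of WT replicate 3, the shallowest. A loss of promoter signal by AMPK-CA alike in all batches is argued against by the mean difference of -0.068 in batches 2 and 3, against -0.62 in batch 1, while a smaller loss outside batch 1 stays open. The 15 promoter regions of housekeeping genes were higher in WT replicate 1 by a median of 0.91, 13 of them higher, where 42 promoter regions of apolipoprotein and coagulation genes had a median of 0.13. The housekeeping median met the prediction set beforehand for more reads from open promoters in general in that library. That median lay near the 0.97 of all regions within 1 kb of a start site, so it largely restates the excess. All regions tested came from the HNF4a ChIP-seq, so open promoters in general and HNF4a sites were not separated. The apolipoprotein and coagulation promoters, 24 of 42 higher, argue against an excess alike at all promoters. How open the promoters were was not measured. Which step of the experiment gave the excess, and whether AMPK-CA replicate 1 of the same batch shared it in part, stays open.

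In 376 pairs of region and library, at most 1 read was found where at least 15 were expected from the other libraries, against 70.5 expected from the fitted dispersion (simulated range 54 to 88). That expectation leaves out the batches. Where the batch partner also predicted at least 15, WT replicate 1 had 61 pairs against 12.9 expected (simulated range 7 to 20). This argues against sampling of few reads there. The other 5 libraries had 22 against 45.96 (simulated range 34 to 60), fewer than the dispersion predicted. These 22 lay in WT replicate 2 (16), AMPK-CA replicate 2 (5) and AMPK-CA replicate 1 (1). Counting of reads alone would give 0.029 pairs in the 5 libraries (Poisson expectation). This argues against counting alone as their source in those libraries. Sampling with the spread between libraries that the dispersion includes cannot be told apart from other sources in them. The 376 pairs lay in WT replicate 1 (170), WT replicate 2 (138), AMPK-CA replicate 2 (66) and AMPK-CA replicate 1 (2), and in 0 of either batch 3 library. The batch 3 libraries had fewer regions with at least 15 reads expected, 11473 in WT and 16142 in AMPK-CA, against 33364 in WT replicate 1. The pairs expected in them were 7.2 and 9.2. Sequence variants of single animals may empty neighbouring regions: 41 neighbouring pairs of such regions in the same library lay within 1 Mb of each other, against a median of 35 and a 95th percentile of 44 in random draws, so variants and other sources cannot be told apart. The Ppp2r2b region, with 0 and 1 reads in AMPK-CA replicates 1 and 2 and 54 in AMPK-CA replicate 3, was singled out after its values were seen.

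Other splits of the libraries were too few for a share under 0.05. Without the block the real split gave 0 regions, so that all 10 of 10 splits had to give as many and the count says nothing of chance; the highest other was 1. With the block, 1 of the 4 splits that part every batch gave as many as the real 23, which was the real split, the highest other being 1. At the preset correlation, 9 of 10 splits gave as many lists as the real 1, the highest other being 5, from the split that sets WT replicates 1 and 2 and AMPK-CA replicate 2 against the rest, a structure of the samples other than genotype.

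The authors' test was recomputed with genotype exchanged within 1 batch, over the 39025 regions above 0 in all 6 libraries, where the recomputed counts equal those of the authors' deposited table. Promoter regions with a score below -0.75 numbered 766 for the real labels, and 95, 608 and 561 with genotype exchanged in batch 1, 2 or 3. Those with a score above 0.75 numbered 113, and 450, 114 and 118 with the exchange, so that higher scores outnumbered lower ones only with the exchange in batch 1. Regions of any annotation with an unadjusted p under 0.05 numbered 4776, and 3920, 3959 and 3799 with the exchange.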
